A study of Homo sapiens with 18 samples.

How the data were processed

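RNA of NT2 cells and of 5 kinds of NT2N neuron culture was measured on 18 one-colour Affymetrix arrays of a focused glycogene panel, from biotin-labelled cRNA per the labels' protocols. The values used are the deposited log2 expression values of 1259 probe sets, made with RMA per the submitters' processing notes. The RMA version and its settings are not given in the sources used here. The log2 scale was read from the values. Detection calls, scanner files and batch labels were not used here, so the brightness at which a probe set stands above background is unknown.

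Groups and replicate numbers came from the sample titles and descriptions, 3 arrays in each of 6 groups. The group called poly-lysine carries BSA in its titles and poly-lysine in its descriptions, and whether BSA was added is not given in the sources used here. Probe sets were named by their RefSeq accession, without its version, in a gene table of GRCh38.p14 used only for names. Of 1259 probe sets, 1069 carried such an accession and 1043 matched, as 927 genes, 93 of them with over 1 probe set. The other 216 were tested without a name. A gene is shown by its probe set with the highest mean over all arrays, and other probe sets are named where they disagree in call or sign. Probe sets ending in _s_at (266) or _x_at (87) can bind related transcripts, ST8SIA4, NCAM1, ERBB3 and IDS among those named.

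Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 18 arrays, contrasts, eBayes), two-sided, with Benjamini-Hochberg adjustment over the 1259 probe sets of a comparison and a threshold of 0.05. There was no filter on dim probe sets. Named genes followed a rule fixed before the data were examined. For neurons on Matrigel against NT2 it took FUT4, FUT9, every fucosyl- and sialyltransferase that passed, the 8 largest rises and 8 largest falls, and the 3 members with the smallest adjusted p from each other list with at least 3 passing members or called by camera. For other comparisons it took FUT9, FUT4, L1CAM and the 6 largest rises and falls, or the 3 genes with the smallest unadjusted p where none passed. Further members named to spell out small counts, or because they did not pass, were chosen after their values were seen. Some genes that this rule selects are not reported here.

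The 30 gene lists were written before the data were examined, and 29 had at least 3 genes on the panel. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and limma's fry as alternatives. In camera a list is compared with the other genes of a chosen panel, not with the genome. In fry a list is tested for a difference between the groups, without comparison with other genes. None of the 19 cell cycle markers listed was on the panel and that list was not tested. Some genes belong to several lists. Alternatives were a replicate block, a fit of only the groups compared, centring each array on its median or on the mean of the 4 housekeeping genes measured (RPL13A, LDHA, RPS18 and GUSB), quantile normalization, removal of 315 dim probe sets, trend and robust eBayes, array weights, a minimum fold change, 1 probe set per gene, and leaving out each array in turn.

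Replicate numbers come from the labels, which do not say what a number marks. Whether they pair the arrays was checked by the correlation of same-numbered arrays' deviations from their group means. For L1 against poly-lysine these were 0.665, 0.654 and 0.861 for numbers 1, 2 and 3, and for L1-Ig5-6 against poly-lysine 0.621, 0.665 and 0.762, so that in both the numbers were taken to pair the arrays. Fitted with a replicate block in limma, these comparisons gave 0 calls each, with 13 and 73 probe sets at an unadjusted p under 0.05.

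The limma comparisons were tested on simulated data in which 200 of 1259 probe sets were changed, camera on data in which 1 list was moved (called, with 1 other of the 29, and 0 called without the change), and the mixing shares on 20 simulated mixtures of 50% (mean shares 50.2% and 48.9%). The reference of the mixing shares was changed to the mean of log2 values after a first result, because simulated mixtures were then recovered, with the same outcome. The mixtures were simulated with a smaller spread than observed and with 1 mean for all neuron groups. In single mixtures the 2 shares differed by -11.6 to 7.61 points. For neurons on Matrigel against NT2, 71.6% of 1.5-fold, 82.1% of 2-fold and 100% of 4-fold changes were recovered, with 10 false calls. For L1-Ig5-6 against poly-lysine the shares were 71.6%, 89.6% and 98.5%. The simulated errors were drawn independently for each array and probe set, without a departure shared by same-numbered arrays. Such a shared departure was present in the deposited values, so the recovered shares and false calls need not hold for them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.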

Results

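Expression was measured on 18 arrays of human NT2 teratocarcinoma cells and of NT2N neurons, which are obtained from NT2 cells by treatment with retinoic acid. The 6 groups of 3 arrays were undifferentiated NT2 cells and neurons grown on poly-lysine with Matrigel, on poly-lysine, or on poly-lysine with the cell adhesion molecule L1 or its truncated forms L1-Ig1-4 and L1-Ig5-6. The labels of the neurons on Matrigel also name mitosis inhibitors in the culture, which no other label mentions. A difference of these neurons from NT2 cells can therefore not be assigned to differentiation alone. The panel held 1259 probe sets for glycosyltransferases, glycan-binding proteins, proteoglycans and signalling molecules, of which 1043 were named as 927 genes. Array medians lay between 6.1 and 6.3 on the log2 scale, and the number of arrays sets the precision of every value. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these arrays.

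The first comparison asked which glycan-synthesis genes differ between neurons and undifferentiated cells, in a series concerned with Lewis x found on the neurons only. Neurons on Matrigel held 24.1-fold more NCAM1, the neural cell adhesion molecule, than NT2 cells (log2 difference 4.59, SE 0.56, adjusted p = 0.000254, n = 3 arrays per group). The proteoglycan lumican, LUM, was 20.1-fold higher and the insulin-like growth factor binding protein IGFBP5 12.6-fold higher, with log2 differences of 4.33 (SE 0.70) and 3.66 (SE 0.50), which were 5.16 and 4.30 without NT2 replicate 3. Neurocan, NCAN, a chondroitin sulfate proteoglycan of the nervous system, rose by 3.27 (SE 0.51), the testican SPOCK2 by 3.12 (SE 0.61; 2.52 without Matrigel replicate 3) and the chemokine CCL2 by 2.92 (SE 0.45). The largest fall was that of the neuregulin receptor ERBB3, at -2.13 (SE 0.37, adjusted p = 0.00218). It was followed by the Wnt receptor FZD5 (-1.72, SE 0.39), the C-type lectins CD302 (-1.70, SE 0.32) and CLEC4D (-1.63, SE 0.29), the growth factor FGF19 (-1.68, SE 0.33) and the fibroblast growth factor receptor FGFR3 (-1.60, SE 0.42). In all, 326 of 1259 probe sets passed, 158 higher and 168 lower, and 258 of 927 genes, 129 in each direction.

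Limits of that count were measured. It was 130 (102 higher, 28 lower) when only these 6 arrays were fitted, 179 without Matrigel replicate 3, 206 without NT2 replicate 1, 145 without the 5 neuron arrays numbered 3 and 277 without all 6 numbered 3, both chosen after seeing the data. Centring each array on 4 housekeeping genes, 3 of which were themselves lower, moved the median difference up by 0.463 and gave 838 calls (781 higher, 57 lower). Of the calls of named genes, 37 were lost in the fit of the 6 arrays alone and 35 without the 5 numbered 3. Without Matrigel replicate 3 the FGFR3 call was lost (-1.17, adjusted p = 0.0670). Second probe sets of NCAM1 (0.01, adjusted p = 0.917) and ERBB3 (-0.24, adjusted p = 0.0645) did not pass.

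Of the 13 fucosyltransferases, 0 were higher, 5 were lower and 8 did not pass limma's test, against 5 higher and 0 lower after centring on the housekeeping genes. FUT9, an α1,3-fucosyltransferase that makes Lewis x, stood at 6.76 ± 1.01 (SD, n = 3) on Matrigel and 5.10 ± 0.058 in NT2 cells, a log2 difference of 1.66 (SE 0.62, 95% interval 0.34 to 2.99) with an adjusted p of 0.0615. FUT4, the other Lewis x-forming enzyme of myeloid and embryonal cells, fell by 0.65 (SE 0.17, adjusted p = 0.0121) from 7.33 in NT2 cells to 6.68. The α1,2-fucosyltransferases FUT1 (-1.07, SE 0.27) and FUT2 (-0.33, SE 0.07), the core fucosyltransferase FUT8 (-0.46, SE 0.12) and POFUT3 (-0.62, SE 0.13), also known as FUT10, were lower, while centring on the housekeeping genes turned FUT2 to 0.14 and FUT8 to 0.01. NT2 replicate 3 held 5.75 of FUT1, within the 5.39 to 5.86 on Matrigel, against 7.22 and 7.11 on NT2 replicates 1 and 2. FUT7 (0.31), POFUT2 (0.35), FUT3 (-0.18), FUT5 (-0.14), FUT6 (0.05), POFUT1 (0.07) and POFUT4 (-0.03) did not pass. Adjusted over the list alone, 7 members passed, 2 higher and 5 lower, and 3 were higher at an unadjusted p under 0.05.

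Without Matrigel replicate 3 the FUT9 difference was 1.08 (adjusted p = 0.276). It passed without Matrigel replicate 2 (2.01, adjusted p = 0.0413), with array weights (1.37, adjusted p = 0.0335), after centring on the housekeeping genes (2.13, adjusted p = 0.0192), and in 2 fits chosen after seeing the data. Those were the fits without the 2 neuron arrays nearest to NT2 (2.01, adjusted p = 0.0254) and without the 5 numbered 3 (1.08, adjusted p = 0.0469). FUT9 also passed with a replicate block (adjusted p = 0.00243). The numbers were not taken to pair Matrigel and NT2 arrays, since same-numbered deviations correlated at -0.152, -0.120 and -0.016. The adjusted p of FUT9 ranged from 0.00243 to 0.276 over all settings. FUT4 missed the threshold without Matrigel replicate 3 (-0.48, adjusted p = 0.0700), in the fit of these 6 arrays alone (adjusted p = 0.0631), without the 5 numbered 3 (adjusted p = 0.0921) and after centring on the housekeeping genes (-0.18, adjusted p = 0.159), with a range from 0.000413 to 0.159. FUT1 missed it without NT2 replicate 1 (adjusted p = 0.0547) or NT2 replicate 2 (adjusted p = 0.0518), and FUT8 without Matrigel replicate 3 (adjusted p = 0.0670), NT2 replicate 1 (adjusted p = 0.0731) or NT2 replicate 2 (adjusted p = 0.0560). The fit of these 6 arrays alone ended the other 4 calls too, with unchanged differences, for FUT1 (adjusted p = 0.125), FUT2 (0.0770), FUT8 (0.138) and POFUT3 (0.0502). FUT1 and FUT8 also missed the threshold without the 5 numbered 3 (0.0565 and 0.114), and FUT1 and POFUT3 after centring on the housekeeping genes (0.0541 and 0.159). Over all settings the adjusted p ranged from 1.39e-06 to 0.125 for FUT1, 0.000157 to 0.317 for FUT2, 0.000277 to 0.967 for FUT8 and 0.000166 to 0.159 for POFUT3. In each of the 5 neuron groups the array numbered 3 held the highest FUT9 value, 7.48 to 8.21 against 5.31 to 7.05 on the other 10 neuron arrays.

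**Figure D1:**
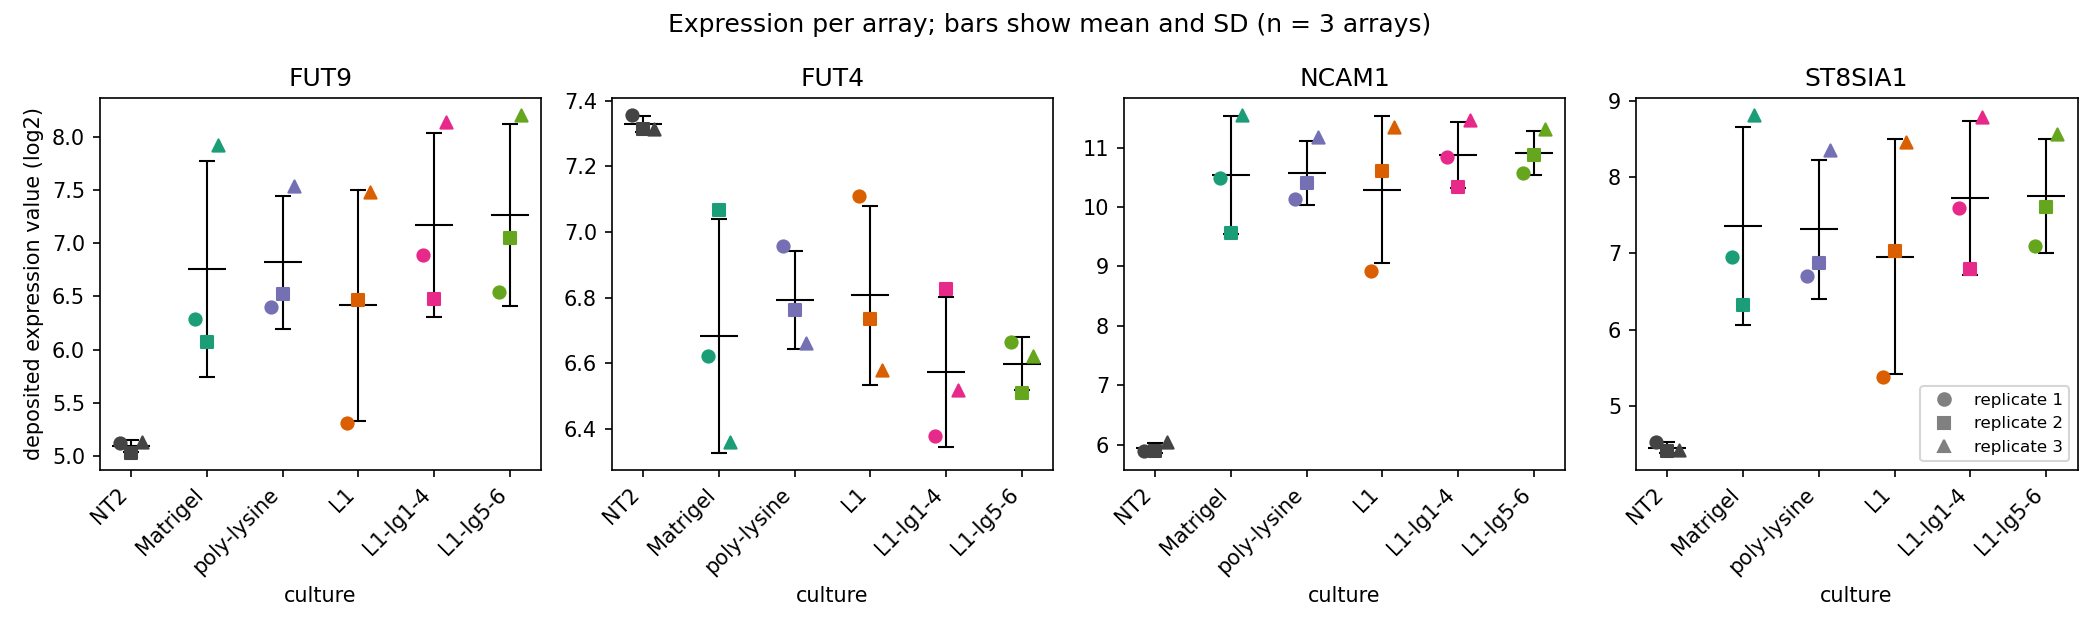
Deposited log2 expression values of FUT9, FUT4, NCAM1 and ST8SIA1 on each of the 18 arrays, by culture, with the mean and SD of 3 arrays; the marker shape gives the replicate number. FUT9 averaged 5.10 in NT2 cells and 6.76 in neurons on Matrigel, and its array numbered 3 was the highest of each neuron group.

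Of the 20 sialyltransferases, 8 were higher, 2 lower and 10 did not pass, with more higher than lower under every scaling tried (17 and 1 after centring on the housekeeping genes). The polysialyltransferases ST8SIA4 and ST8SIA2, which build polysialic acid on NCAM, rose by 2.96 (SE 0.61, adjusted p = 0.00389) and 2.77 (SE 0.46, adjusted p = 0.00164). Among ganglioside sialyltransferases, the GD3 synthase ST8SIA1 rose by 2.91 (SE 0.78, adjusted p = 0.0135), the GM3 synthase ST3GAL5 by 2.04 (SE 0.28, adjusted p = 0.000723) and ST8SIA5 was 2.70-fold higher (SE 0.48 on the log2 scale, adjusted p = 0.0414). ST8SIA3 (1.53, SE 0.37), ST3GAL3 (1.07, SE 0.21) and ST6GALNAC3 (0.42, SE 0.14) were also higher. ST6GAL1, which adds α2,6-linked sialic acid to N-glycans, fell by 0.89 (SE 0.16, adjusted p = 0.00292) and ST6GALNAC2, which acts on O-glycans, by 0.86 (SE 0.25). NT2 replicate 3 held 5.02 of ST6GALNAC2, within the 4.93 to 5.18 on Matrigel, against 6.34 and 6.35 on NT2 replicates 1 and 2. Adjusted over the list alone, 11 passed, 9 higher and 2 lower. The camera test of the list against the other genes of the panel gave an adjusted p of 0.133.

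The ST8SIA1 call was lost without Matrigel replicate 3 (2.18, adjusted p = 0.0784), and that of ST8SIA5 without any 1 of the 6 arrays (adjusted p from 0.0563 to 0.145). ST6GALNAC2 missed the threshold without Matrigel replicate 1, NT2 replicate 1 or NT2 replicate 2 (adjusted p = 0.0598, 0.105 and 0.103). ST6GALNAC3 missed it without any 1 array other than Matrigel replicate 2 (adjusted p from 0.0676 to 0.166), and in 10 of 17 settings in all. The fit of the 6 arrays alone ended the calls of ST6GALNAC2 (adjusted p = 0.167) and ST6GALNAC3 (0.0590), and leaving out the 5 numbered 3 ended those of ST8SIA3 (0.0555), ST6GALNAC2 (0.0867) and ST6GALNAC3 (0.148). The array numbered 3 was the highest of each neuron group for ST8SIA1, ST8SIA2, ST8SIA3, ST8SIA4 and ST6GALNAC3, and the lowest for ST8SIA5. The other probe sets of ST8SIA4 averaged 2.46 and 2.52, at the lowest values of the arrays. They showed no rise in limma's test (-0.04 and 0.03, adjusted p = 0.679 and 0.786), and the cause of this disagreement was not tested.

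**Figure D2:**
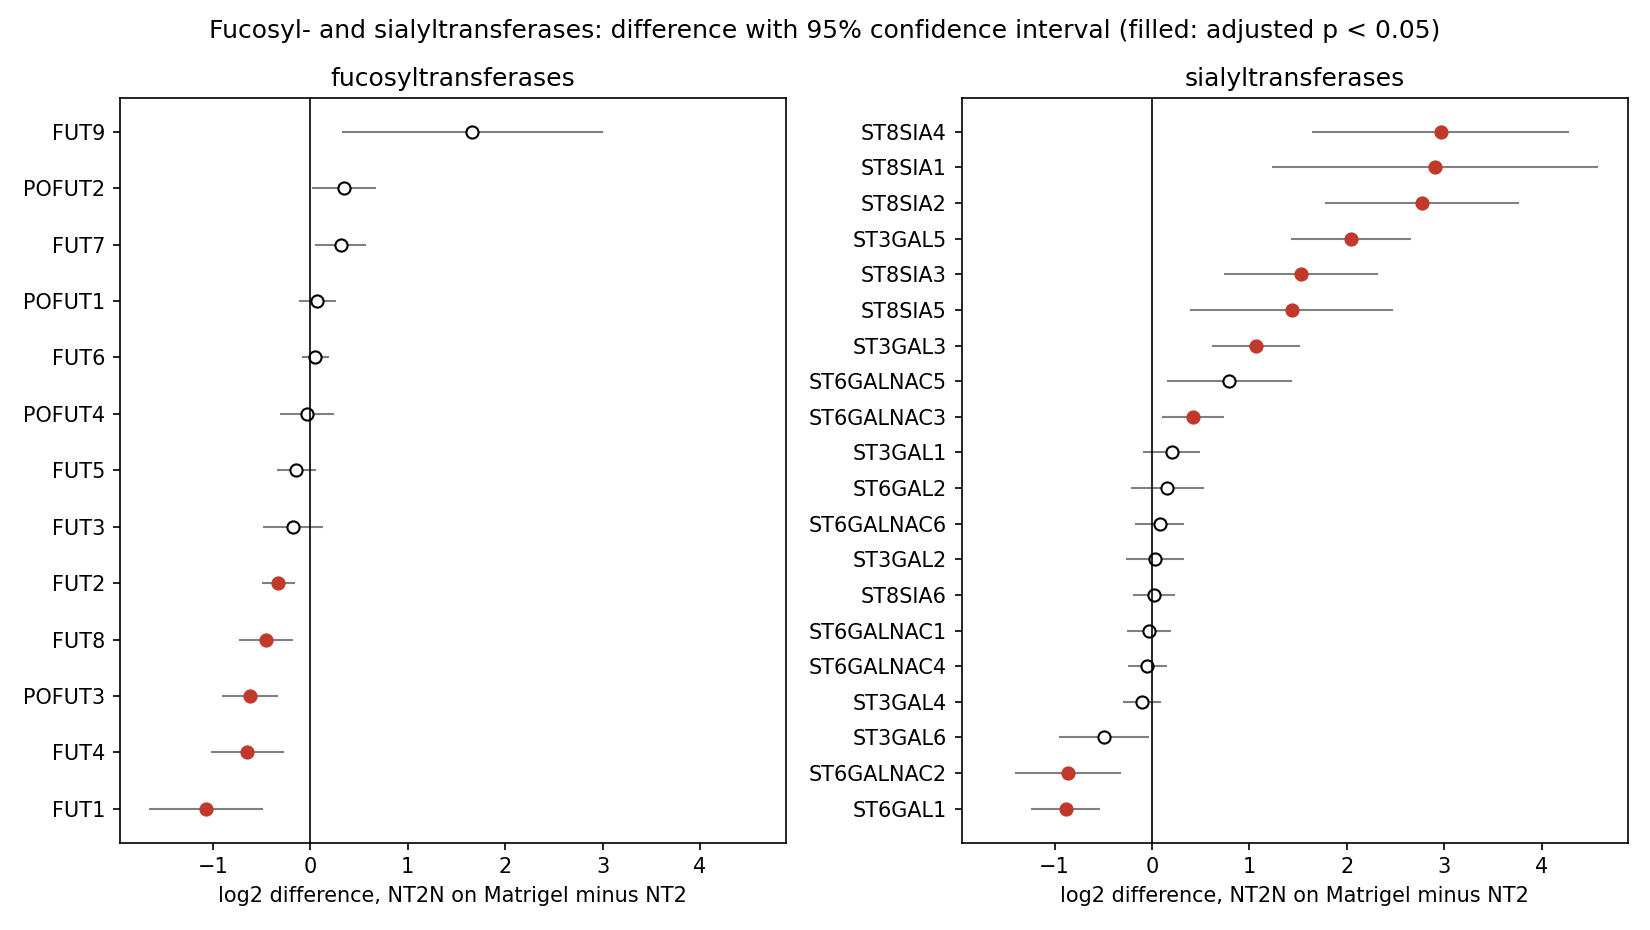
Log2 differences, neurons on Matrigel minus NT2, of 13 fucosyltransferases and 20 sialyltransferases with 95% confidence intervals; filled points have an adjusted p under 0.05. On the deposited values 5 fucosyltransferases were lower and 0 higher, and 8 sialyltransferases were higher and 2 lower. After centring on the housekeeping genes 5 other fucosyltransferases were higher and 0 were lower.

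All 4 neuronal markers on the panel were higher, NCAM1, NCAN, ST8SIA3 and the granule protein CHGA (1.03), and all 4 passed adjusted over the list alone, while 3 were higher with each array centred on its median. This was the only list of 29 that camera called (adjusted p = 0.00784), and the call was lost with an estimated correlation (adjusted p = 0.737). Of 5 neural adhesion molecules and L1 partners, NCAM1 and NCAN rose, and the receptors FGFR1 (-0.997, SE 0.25) and PTPRZ1 (-1.41) fell (4 adjusted over the list alone), against 3 higher and 2 lower after centring on the housekeeping genes. Of 7 mesenchymal markers, LUM and the hyaluronan receptor CD44 (1.98, SE 0.37) rose together with the neuronal genes, and PDGFRA (-0.79, SE 0.21) fell, against 4 higher and 1 lower after centring on the housekeeping genes, and 3 passed adjusted over the list alone. The embryonal growth factor FGF4 (-0.35) was the 1 of 3 pluripotency markers that passed (2 adjusted over the list alone), and did not after centring on the housekeeping genes. GAL3ST1 (-0.66, SE 0.16), a sulfotransferase of myelin sulfatide, was the 1 of 5 glial markers that fell (3 adjusted over the list alone, 1 higher and 2 lower), with 2 higher and 0 lower after that centring. The housekeeping genes RPL13A (-0.88, SE 0.25), LDHA (-0.55, SE 0.15) and GUSB (-0.28, SE 0.09) were lower, with GUSB at 0.19 without passing, 1 higher (RPS18) and 1 lower (RPL13A) once centred on the list itself, and 3 of 4 passed adjusted over the list alone. Calls were lost without Matrigel replicate 3 for FGFR1 (adjusted p = 0.0562), PDGFRA (0.0767), RPL13A (0.0943), LDHA (0.0854) and GUSB (0.101). They were lost without NT2 replicate 1 for PDGFRA (0.05001), RPL13A (0.0725), LDHA (0.0580) and GUSB (0.145), and without NT2 replicate 2 for PDGFRA (0.0543), RPL13A (0.0560) and GUSB (0.173). GUSB also missed the threshold without Matrigel replicate 1 (0.0760) or 2 (0.0764).

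Of 18 genes of glycosphingolipid and ganglioside synthesis, 8 were higher and 3 lower (3 and 3 after quantile normalization, 14 and 1 after centring on the housekeeping genes), and 14 passed adjusted over the list alone. ST3GAL5, ST8SIA1 and ST8SIA5 were among the higher, and the lactosylceramide synthase B4GALT6 (-0.85, SE 0.17) and GAL3ST1 among the lower. Of 18 transferases listed for the lactosamine chain, which carries Lewis x, 4 were higher and 6 lower (10 and 1 after centring on the housekeeping genes), and 12 passed adjusted over the list alone. B4GAT1 (0.93, SE 0.21), whose name is that of a glucuronyltransferase, rose, while the I-branching enzyme GCNT2 (-0.63, SE 0.12) and B4GALT6 fell. Membership of this list does not show that B4GAT1 or B4GALT6 acts on the chain that carries Lewis x. Of 6 genes of GDP-fucose supply and fucosidases, 3 were higher and 1 lower (5 and 0 after that centring), and 4 passed adjusted over the list alone. These were the GDP-fucose synthase GFUS (0.98, SE 0.25), the GDP-fucose transporter SLC35C1 (0.54), the fucosidase FUCA1 (1.39, SE 0.34) and, lower, the GDP-mannose dehydratase GMDS (-0.57, SE 0.14). GFUS missed the threshold without Matrigel replicate 1 (adjusted p = 0.0593) or NT2 replicate 1 (adjusted p = 0.0569). Of 10 genes of sialic acid supply, 0 were higher in limma's test or at an unadjusted p under 0.05 and 3 were lower, as they were adjusted over the list alone, against 5 higher and 0 lower after centring on the housekeeping genes. They were the synthase NANS (-0.41, SE 0.12, turned to 0.05 by that centring), the activating enzyme CMAS (-0.51, SE 0.14) and the lyase NPL (-0.90, SE 0.26). CMAS was lost without Matrigel replicate 1 (adjusted p = 0.0565) or NT2 replicate 1 (0.0726), NANS without Matrigel replicate 1 or 3 or NT2 replicate 1 or 2 (up to 0.122), and NPL without Matrigel replicate 1 or 3 or NT2 replicate 1 or 3 (up to 0.119).

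Of 14 genes of N-glycan trimming and branching, 3 were higher and 0 lower (11 and 0 after centring on the housekeeping genes, 2 and 1 with each array centred on its median), and 3 passed adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 in limma's test. These were the mannosidases MAN2A2 (1.10, SE 0.29) and MAN1A2 (0.26, SE 0.07) and MGAT3 (0.71, SE 0.24), which adds the bisecting N-acetylglucosamine. Of 22 genes of N-glycan precursor assembly, 1 was higher (ALG11, 0.94) and 4 lower, 5 adjusted over the list alone, against 11 and 0 after centring on the housekeeping genes. Among the lower were the glucosyltransferase ALG6 (-0.78, SE 0.19), the phosphomannomutase PMM2 (-0.64, SE 0.20) and the isomerase MPI (-0.45, SE 0.12, turned to 0.01 by that centring). Of 22 genes of mucin-type O-glycan synthesis, 5 were higher and 3 lower (4 and 4 after quantile normalization, 16 and 3 after centring on the housekeeping genes), and 9 passed adjusted over the list alone. GALNT9 (1.65, SE 0.26) rose, and GALNT12 (-1.06, SE 0.21) and the core 2 enzyme GCNT1 (-1.60, SE 0.30) fell. Of 11 genes of O-mannose and O-fucose glycans, POMT1 (0.94, SE 0.21) was higher and LARGE2 (-0.75, SE 0.15) and the Notch-modifying LFNG (-0.88, SE 0.27) lower, 7 being higher and 2 lower after centring on the housekeeping genes, and 5 passed adjusted over the list alone. A second LFNG probe set gave -0.31 (adjusted p = 0.0610). Without Matrigel replicate 3, calls were lost for MAN2A2 (adjusted p = 0.0678), ALG6 (0.0547), MGAT3 (0.213), PMM2 (0.144), MPI (0.0773) and LFNG (0.131). MGAT3 and PMM2 were also lost without any 1 array other than Matrigel replicate 2 (up to 0.213 and 0.144), MPI without NT2 replicate 1 or 2 (up to 0.0773), LFNG without Matrigel replicate 1 or NT2 replicate 1 or 2 (up to 0.131), and MAN1A2 without Matrigel replicate 1 or NT2 replicate 2 or 3 (up to 0.0767). Over all 17 settings the calls of MGAT3 and PMM2 were each lost in 8.

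Of 30 genes of heparan sulfate synthesis and sulfation, 10 were higher and 1 lower (HS3ST6, -0.26), against 21 and 0 after centring on the housekeeping genes, and 13 passed adjusted over the list alone, 11 higher and 2 lower. The N-deacetylase/N-sulfotransferase NDST3 rose by 1.89 (SE 0.27), the 3-O-sulfotransferase HS3ST4 by 0.92 (SE 0.19) and the linker galactosyltransferase B3GALT6 by 0.90 (SE 0.15). The camera adjusted p of this list was 0.0689, against 0.0359 without NT2 replicate 1 and 0.0389 with each array centred on its median, and with an estimated correlation the adjusted p was 0.737. Of 25 genes of chondroitin, dermatan and keratan sulfate synthesis, 5 were higher and 8 lower (14 and 5 after centring on the housekeeping genes), and 15 passed adjusted over the list alone. The epimerase-like DSEL (1.57, SE 0.25) rose, and the sulfotransferases CHST2 (-1.50, SE 0.28) and UST (-1.28, SE 0.25) fell. Of 27 proteoglycan core proteins, 5 were higher and 3 lower (17 and 1 after that centring), and 8 passed adjusted over the list alone. LUM, NCAN, SPOCK2, agrin AGRN (0.86) and glypican-1 GPC1 (1.20, SE 0.18) rose, and GPC3 (-0.70), PTPRZ1 and TGFBR3 (-0.45) fell. Of 8 hyaluronan genes, CD44, HYAL1 (0.46, SE 0.10) and HYAL3 (0.97) were higher and HYAL2 (-0.34, SE 0.08) lower, with HYAL2 at 0.12 and 5 higher and 0 lower after centring on the housekeeping genes, and 4 passed adjusted over the list alone.

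The series also asked for Lewis x-binding proteins. Of 13 lectins with fucosylated ligands, 0 passed limma's test in either direction, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05, the asialoglycoprotein receptor subunit ASGR1 (0.65, adjusted p = 0.0643) and CLEC4F (0.27, adjusted p = 0.0818). The selectins SELE (-0.05) and SELP (-0.05), CD209 (-0.09) and CD207 (-0.07) did not pass, but 8 lectins of this list were higher after centring on the housekeeping genes. Of 14 siglecs, which bind sialic acid, 0 passed limma's test, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, against 12 higher after that centring. Of 13 galectins and related proteins, the β-galactoside-binding LGALS3 (1.86, SE 0.36) and its ligand LGALS3BP (2.03, SE 0.46) rose and LGALS12 (-0.38, SE 0.13) and LGALS13 (-0.21) fell, 4 adjusted over the list alone, with LGALS12 at 0.08 and 7 members higher and 0 lower after the centring. The LGALS12 call was lost without Matrigel replicate 1 or 3 or NT2 replicate 1 or 2 (adjusted p from 0.127 to 0.218).

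Of 55 growth factors and receptors, 7 were higher and 15 lower (29 and 9 after centring on the housekeeping genes), and 26 passed adjusted over the list alone. NRG1, a neuregulin that binds ERBB3, was 4.92-fold higher (SE 0.33 on the log2 scale), VEGFB rose by 1.51 (SE 0.26), and the neurotrophin BDNF fell by 0.80 (SE 0.15). The other NRG1 probe sets gave 0.54 and 0.37 (adjusted p = 0.129 and 0.0562). Of 28 Wnt and hedgehog genes, 2 were higher and 5 lower (12 and 3 after that centring), and 8 passed adjusted over the list alone. WNT3 rose by 0.78 (SE 0.14), and the receptors FZD7 (-0.99, SE 0.22) and FZD4 (-0.49, SE 0.11) fell. Of 9 Notch receptors and ligands, JAG2 (0.48) was higher and NOTCH1 (-0.51) lower, 2 adjusted over the list alone, with 4 higher and 0 lower after the centring, 0 and 3 after quantile normalization and 1 and 2 with each array centred on its median. Of 45 chemokines, cytokines and receptors, 4 were higher and 1 lower (34 and 1 after the centring), and 5 passed adjusted over the list alone. CCL2, CXCL6 (2.54), CXCR4 (1.21) and LIF (1.34, SE 0.27), the leukemia inhibitory factor, rose, and CXCL12 (-1.57, SE 0.33), the ligand of CXCR4, fell. Of 25 lysosomal glycosidases and sulfatases, 6 were higher and 4 lower (6 and 7 after quantile normalization, 12 and 2 after centring on the housekeeping genes), and 11 passed adjusted over the list alone. The iduronate sulfatase IDS rose by 2.05 (SE 0.41). Of 31 genes of nucleotide sugar synthesis and transport, 4 were higher and 6 lower (14 and 3 after centring on the housekeeping genes), and 10 passed adjusted over the list alone. NAGK (0.74, SE 0.17) and the sulfate donor transporter SLC35B3 (0.64, SE 0.15) rose, and GFPT1 (-0.95, SE 0.18), the first enzyme of hexosamine synthesis, fell.

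In 6 lists the median, the mean and the direction of the camera test differed in sign. The lactosamine chain (median 0.02, mean 0.09) and the Notch genes (median 0.000436, mean 0.000639) were placed lower by the test, as were the chondroitin sulfate genes (median 0.07, mean -0.03). The galectins (median -0.06, mean 0.22) and the lectins with fucosylated ligands (median -0.05, mean 0.01) were placed lower too, and the lysosomal enzymes (median -0.06, mean 0.17) higher.

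Taking all 5 neuron cultures against NT2 cells, FUT9 was 3.46-fold higher (log2 difference 1.79, SE 0.48, adjusted p = 0.00781; 15 neuron and 3 NT2 arrays) and FUT4 fell by 0.64 (SE 0.13, adjusted p = 0.00147). The fit counts the 15 neuron arrays as independent. Deviations of same-numbered arrays correlated between neuron cultures, however, at 0.762 to 0.863 for number 3. The SEs and adjusted p of this comparison can therefore be too small. The FUT4 call was lost after centring on the housekeeping genes (-0.18, adjusted p = 0.0675), a setting that moved the median of all probe sets by 0.453. The largest rises were those of NCAM1 (4.69, SE 0.43), LUM (4.30, SE 0.54), IGFBP5 (3.76, SE 0.39), NCAN (3.37, SE 0.39), SPOCK2 (3.23, SE 0.47) and ST8SIA4 (3.09, SE 0.47), with LUM at 5.13 and IGFBP5 at 4.39 without NT2 replicate 3. The largest falls were those of ERBB3 (-2.09, SE 0.29), FGF19 (-1.76, SE 0.26), FZD5 (-1.67, SE 0.31), CD302 (-1.67, SE 0.25), GCNT1 (-1.62, SE 0.23) and CLEC4D (-1.60, SE 0.23). Of the fucosyltransferases, FUT9, FUT7 (0.36) and POFUT2 (0.39) were higher and 5 lower, and of the sialyltransferases 9 were higher and 3 lower. The lectins CLEC4F (0.22) and ASGR1 (0.74) were higher. In all, 517 probe sets passed, 250 higher and 267 lower, and 400 genes (203 higher, 197 lower), against 1018 (943 higher, 75 lower) after centring on the housekeeping genes. Against the same 3 NT2 arrays, 326 probe sets passed in neurons on Matrigel, 301 on poly-lysine, 286 on L1, 430 on L1-Ig1-4 and 499 on L1-Ig5-6. FUT9 passed on L1-Ig1-4 (2.07, adjusted p = 0.0179) and L1-Ig5-6 (2.17, adjusted p = 0.0133) and did not on poly-lysine (1.73, adjusted p = 0.0575) or L1 (1.32, adjusted p = 0.142), and none of the differences between these cultures passed for FUT9.

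The remaining comparisons asked whether the growth substrate altered expression in the neurons, with the poly-lysine group set against L1 and its fragments. The titles of that group read BSA while its descriptions name poly-lysine only, and no label calls it a control, so a difference from it is that between these cultures as labelled. Only the Matrigel labels name mitosis inhibitors, so poly-lysine against Matrigel may hold more than a difference in substrate. UGCG, the glucosylceramide synthase that starts glycosphingolipid synthesis, differed by -0.47 (SE 0.15, adjusted p = 0.9999) between poly-lysine and Matrigel. From poly-lysine it differed by 0.44 on L1 (adjusted p = 0.9998), 0.55 on L1-Ig1-4 (adjusted p = 0.998) and 0.56 on L1-Ig5-6 (adjusted p = 0.935), with the same SE. These 4 differences share the 3 poly-lysine arrays and are not independent. They come from a fit without a replicate block, where the departure of the arrays numbered 3 enters the error. For UGCG the lowest limma adjusted p over the settings tried was 0.287 against Matrigel, 0.997 on L1, 0.127 on L1-Ig1-4 and 0.0863 on L1-Ig5-6. High adjusted p here do not show that a substrate had no effect. FUT9 differed by 0.06 between poly-lysine and Matrigel, and from poly-lysine by -0.40 on L1, 0.35 on L1-Ig1-4 and 0.44 on L1-Ig5-6 (SE 0.62 each). FUT4 differed by 0.11, 0.01, -0.22 and -0.19 (SE 0.17) in the same order. L1-Ig1-4 and L1-Ig5-6 differed by -0.10 in FUT9 and -0.02 in FUT4. L1CAM itself was not analysed here.

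Other genes with the smallest unadjusted p in these comparisons did not pass either. They were the globotriaosylceramide synthase A4GALT (0.23, SE 0.09) and the chemokine receptor CCR9 (-0.20, SE 0.07) between poly-lysine and Matrigel, and FGF18 (0.24, SE 0.10) and the glypican GPC6 (0.38, SE 0.15) between L1 and poly-lysine. Between L1-Ig1-4 and poly-lysine they were BMP8B (-0.30, SE 0.10) and TGFBRAP1 (0.54, SE 0.19), and between L1-Ig5-6 and poly-lysine the oxidised LDL receptor OLR1 (1.37, SE 0.43) and the ceramidase ACER2 (-0.21, SE 0.06). Between L1-Ig1-4 and L1-Ig5-6 they were AMHR2 (0.21, SE 0.08), B3GNT3 (0.16, SE 0.06) and CLEC6A (0.20, SE 0.08). Among these genes the lowest limma adjusted p over the settings tried was 0.0768, for OLR1.

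With limma, 0 probe sets passed in each of the 5 comparisons, and those with an unadjusted p under 0.05 numbered 11 for poly-lysine against Matrigel, 8 for L1, 16 for L1-Ig1-4, 51 for L1-Ig5-6 and 7 between the fragments, where chance alone gives 62.95. Over the settings tried these counts ran from 3 to 98, 1 to 32, 7 to 141, 17 to 144 and 0 to 19 in that order, with 0 calls in each setting. They passed 62.95 with array weights for poly-lysine against Matrigel (98), L1-Ig1-4 (141) and L1-Ig5-6 (144), and for L1-Ig5-6 also with only its arrays and those of poly-lysine fitted (63), with a replicate block (73, or 103 among neuron arrays alone, chosen after seeing the data) and without L1-Ig5-6 replicate 1 (88). Leaving out poly-lysine replicate 1 gave 5 for poly-lysine against Matrigel, 4 for L1 and 19 for L1-Ig5-6, and leaving out replicate 2 gave 5, 5 and 29, with 9 for L1-Ig1-4. Leaving out poly-lysine replicate 3 gave 17 against Matrigel and 33 for L1-Ig1-4, and leaving out Matrigel replicate 2 gave 26. The L1 count was 32 without L1 replicate 3 and 19 without L1 replicate 1, that of L1-Ig1-4 was 47 without its replicate 2 and 7 without its replicate 3, and that of L1-Ig5-6 was 22 without its replicate 3. Between the fragments it was 14 without L1-Ig5-6 replicate 1, 4 without L1-Ig1-4 replicate 2 and 12 without L1-Ig1-4 replicate 3. An F test over the 5 neuron groups also called 0, with 18 at an unadjusted p under 0.05, in a limma fit without a replicate block, where the spread of the arrays numbered 3 enters the error. With the block, among neuron arrays alone and chosen after seeing the data, it called 0 with 73 at an unadjusted p under 0.05. For the median probe set the 95% interval reached 0.264 on either side of a difference, and 0.208 with that block.

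On the first principal component the arrays separated by cell type, and on the second the neuron arrays numbered 3 stood apart from the other neurons. The first principal component held 67.9% of the variance, with the NT2 arrays at 17.2 to 20.9 and the neurons between -9.16 and 8.59. Nearest to NT2 were L1 replicate 1 at 8.59 and Matrigel replicate 2 at 3.59. The second component held 16.3%, and on it the 5 neuron arrays numbered 3 lay at 5.64 to 8.01 and the other neurons between -6.33 and -2.58. Each of the 15 neuron arrays correlated best with an array of another group, and 7 of them with one of the same number, among these all 5 numbered 3. NT2 replicate 3 correlated best with a neuron array, L1 replicate 1 (r = 0.992), above its mean correlation with the other NT2 arrays (0.989). No 2 arrays were identical, the highest correlation being 0.999.

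**Figure D3:**
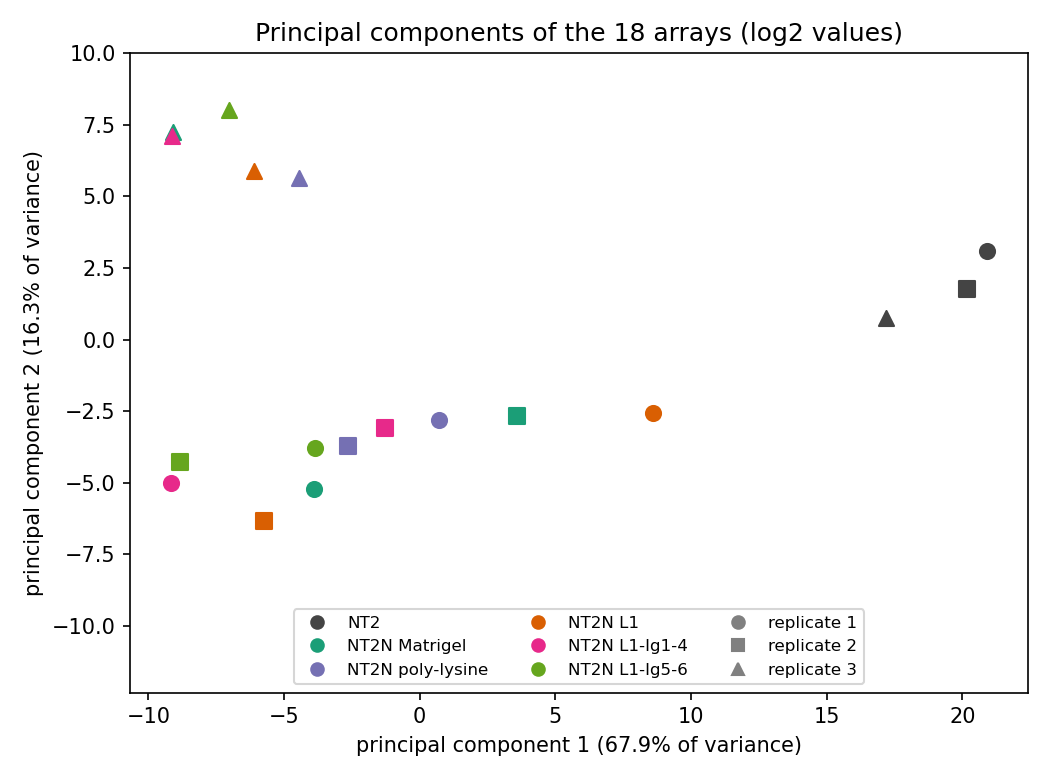
First and second principal components of the 18 arrays from the deposited log2 values, with 67.9% and 16.3% of the variance; colours give the culture and marker shapes the replicate number. The 3 NT2 arrays lie at 17.2 to 20.9 on the first axis, and the 5 neuron arrays numbered 3 at 5.64 to 8.01 on the second.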

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

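The fits without the 5 neuron arrays numbered 3, without all 6 arrays numbered 3, without the 2 neuron arrays nearest to NT2 and of neuron arrays alone with a replicate block were chosen after seeing the data; the other settings of these comparisons were planned. For neurons on Matrigel against NT2, the 326 calls became 130 with only these 6 arrays fitted, 145 without the 5 numbered 3 (277 without all 6), 838 after centring on the housekeeping genes and 105 at a fold change of at least 2. Leaving out 1 array gave 179 to 376, the lowest without Matrigel replicate 3, with 206 without NT2 replicate 1. The fold change bound lowered the count by construction. For the fits of fewer arrays the cause was not tested, and the count rose to 398 without the 2 arrays nearest to NT2. For all neurons against NT2, the 517 calls became 1018 after the same centring and 125 at a fold change of at least 2, and 387 to 551 without 1 array. The 5 comparisons between neuron cultures gave 0 calls with limma in every setting, leaving out 1 array included, with 11, 8, 16, 51 and 7 at an unadjusted p under 0.05 on the deposited values.

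Centring on the housekeeping genes rests on 4 genes, 3 of which fell themselves, and raised the share of calls that were higher from 48.5% to 93.2%. It reversed FUT2 (0.14), FUT8 (0.0054), GUSB (0.19), HYAL2 (0.12), LGALS12 (0.081), MPI (0.0116) and NANS (0.054), by construction, since every difference moved up by the same 0.463. Of 29 gene lists, camera called 1 on the deposited values, 2 with each array centred on its median, 0 after centring on the housekeeping genes and 0 with an estimated correlation. Leaving out 1 array gave 1 to 2 with camera, with 2 without NT2 replicate 1, where heparan sulfate synthesis was called too. Limma's fry asks another question, without comparison with the other genes, and called 13. Among these were the fucosyltransferases, lower (fry adjusted p = 0.00701), and the sialyltransferases, higher (0.0131).

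A replicate block gave 415 calls for neurons on Matrigel, with FUT9 past the threshold (adjusted p = 0.00243, in a range of 0.00243 to 0.276), and 606 for all neurons. It changed no other call among the named genes. Of 95 named gene results that passed, 44 did so in every setting and 51 lost the call in at least 1, 37 of them with only the compared groups fitted and 35 without the 5 arrays numbered 3. Of 26 that did not pass, FUT9 was the 1 that passed in another setting. Removing dim probe sets (mean under 4.65) left no value for 6 named genes. Where 1 array was left out, the other arrays' spread was pooled. How far dim signals stand above background is unknown.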

Other observations

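Planned before the results were seen were the splits of the 7 comparisons and the test by quantile normalization; all other tests in this part, among them those on mixing, on a shared batch, on noise and on other choices of 1 array per group, were chosen only after the result was seen.

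Among the neuron arrays, those numbered 3 held more FUT9 (1.46 on the log2 scale, adjusted p = 5.29e-05) and more ST8SIA1 (1.76, adjusted p = 0.000272), ST8SIA4 (1.29) and ST8SIA2 (0.89) than those numbered 1 and 2, 5 against 10 arrays fitted within their cultures. The neuronal markers NCAM1 (1.09, adjusted p = 0.00663) and NCAN (1.06), the receptor ERBB4 (1.83) and the testicans SPOCK2 (1.31) and SPOCK3 (1.37) were higher as well. The chemokines CXCL1 (-1.67) and CXCL8 (-1.48), the galectin LGALS1 (-1.63, adjusted p = 3.76e-06), the adhesion molecule ICAM1 (-1.14) and the mesenchymal markers LUM (-0.96) and PDGFRB (-0.56) were lower, while the mesenchymal marker VCAN (0.25) was higher. All 4 neuronal markers and 9 of 20 sialyltransferases were higher (3 lower), and of 7 mesenchymal markers 1 was higher and 3 lower. FUT4 differed by -0.21 (adjusted p = 0.146). These genes were named after their values were seen. In all, 417 of 1259 probe sets passed with limma, 183 higher and 234 lower, between 308 and 455 in the settings tried, and 405 (348 higher, 57 lower) after centring on the housekeeping genes. The arrays numbered 1 and 2, tested in the same way, gave 0 each. In those 2 fits the departure of the arrays numbered 3 enters the error, so 0 calls do not show that numbers 1 and 2 are alike.

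Of 100 drawn ways of taking 1 array from each neuron group, out of 243, only 1, the real one with 417 calls, gave as many, and the highest other gave 279. The arrays numbered 3 were tested because they had been seen to stand apart, which by itself favours the real choice. These draws therefore do not exclude chance. After quantile normalization 375 passed, which argues against a shift of whole arrays as the whole cause. A lower share of NT2 cells would move genes away from their NT2 level, and of 201 probe sets that could show it 68.2% did so (interval 61.2% to 74.5%). That interval counts probe sets as independent, which they are not, and does not measure the spread between arrays. The other 64 moved towards NT2, which argues against this as the whole cause on these arrays. A batch shared by every array numbered 3 stays open, since the departure of the 1 NT2 array numbered 3 did not correlate with that of the neurons (r = -0.00258) but the labels name no batch and NT2 cells may have been handled apart. No biological explanation was tested.

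L1 replicate 1 and Matrigel replicate 2 were the neuron arrays nearest to NT2. If RNA of NT2 cells had been mixed in, probe sets high in NT2 and those high in neurons would give the same share. They gave 38.9% and 70.6% for L1 replicate 1, a difference of -31.7 points (interval -42.2 to -22.9), and 28.5% and 47.8% for Matrigel replicate 2, -19.3 points (-26.8 to -12.9), which argues against such mixing as the whole cause if signal is proportional to RNA. All intervals of these shares resample probe sets within 1 array and do not measure the spread between arrays. L1 replicate 1 had rank 1 of 10 in spread over 217 probe sets that did not differ between NT2 and neurons, and Matrigel replicate 2 rank 4. Noise without a direction would leave both shares near 0 on an array taken at random. The smaller shares, 38.9% (interval 30.4% to 45.6%) and 28.5% (22.2% to 34.6%), lay above 0. Both arrays were chosen for lying nearest to NT2, which by itself makes such shares positive. This test therefore cannot decide on noise, and no biological explanation was tested.

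NT2 replicate 3 held more LUM (2.48 above the other NT2 arrays), IGFBP5 (1.90), the stem cell factor KITLG (1.59) and the CXCL12 receptor CXCR4 (1.60), and less ICAM1 (-1.90), FUT1 (-1.41), GCNT1 (-1.34) and ERBB3 (-1.30). If RNA of whole neuron cultures had been mixed in, the neuronal markers would show the same share as LUM (11.9%) and IGFBP5 (13.1%). The highest, NCAN, gave 3.45%, CHGA gave 1.54%, NCAM1 0.364% and ST8SIA3 -16.7%. LUM and IGFBP5 were chosen for their rise on this array, which by itself makes their shares high. The marker shares therefore argue only against mixing at the shares of LUM and IGFBP5, and cannot decide on a smaller share. RNA of the non-neuronal cells of such cultures may remain a source and was not tested; no biological explanation was tested either.

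Among the comparisons, with 6 arrays there are 10 splits, too few to give a share under 0.05. For neurons on Matrigel against NT2, 1 of 10 splits gave as many calls, the real one with 130 when these 6 arrays were fitted alone (326 with all 18) against 0 for the highest other. In the 5 comparisons between neuron cultures 10 of 10 gave as many as the real count of 0, and the highest other gave 2 for L1 against poly-lysine and 0 for the remaining 4. For all neurons against NT2, fitted as 2 groups of 15 and 3 arrays instead of the 6 groups that gave 517 calls, 1 of 100 drawn splits out of 816 gave as many. This was the real one with 559 calls. The highest other gave 345 and took Matrigel replicate 2 with NT2 replicates 1 and 2 as the NT2 group. These draws argue against chance if the arrays are independent. The labels do not show that they are, so chance is not excluded.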
